A study of Mus musculus with 20 samples.

How the data were processed

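RNA was measured in microglia sorted from brains of WT and 5XFAD mice that drank water or metronidazole, with 5 libraries in each of the 4 groups. Per the labels, 1000 sorted cells were lysed for each library, cDNA was made by the Smart-seq2 protocol, and 2 reads of 25 bp per fragment were sequenced on a NextSeq500. The labels do not state the animals per library, their sex or the sorting gates, so p-values measure the spread between samples. The deposited count table gives the signal as the authors' normalized counts, with 2969 named genes and 1 entry without a name, which was left out. The authors' comparison tables hold, per the file headers, the mean normalized count of each gene (baseMean, another unit of level), the log2 fold change with its SE, the test statistic (a score), the p-value and the adjusted p-value. The submitters' processing notes name DESeq2 with no version, and the aligner, genome build and annotation are not given in the sources used here. The authors' tables list no gene with a mean under 100, and the lowest gene mean in the count table was 99.9.

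The raw counts could not be recovered from the normalized ones, so no count-based tool was run, and the depth per library is unknown. The sums of the deposited values, between 1655880 and 3502550 normalized counts per library, are therefore not read counts, and no counting interval is given.

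Genes were kept when their mean over the 20 libraries was at least 10 normalized counts, which all 2969 met. The values were analysed as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted over all 20 libraries (16 residual degrees of freedom) and a variance trend on the mean level. The comparisons were 5XFAD against WT on water and with metronidazole, metronidazole against water in WT and in 5XFAD, the average of the last 2, and the interaction. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Single measures per library (levels, shares, component scores, marker scores) were compared by 2-sided exact permutation tests over the 252 arrangements of 5 against 5, of which the smallest p is 0.00794. The 16 tests of library measures and the 32 of marker scores were adjusted within their family. The exact p-values of single genes were not adjusted. Those genes were named from their limma results in the same libraries, so a full separation of groups is no separate check. No paired analysis was possible because nothing in the labels pairs the libraries.

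Gene lists, 35 in number, were fixed before the data were examined, as were the groups, the comparisons, the tests and the rule for named genes. The 18 lists of microglial states and pathways with at least 5 measured genes were tested in each comparison with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, giving 108 tests of which 30 passed. The named genes include App and Thy1, the 10 highest and 10 lowest log2 changes past the threshold with a mean of at least 20 in the higher group (clone-type names left out), the members of smallest p of the lists, and the 2 highest markers of each other cell type. Where fewer than 10 genes passed, the 5 genes of smallest p per direction were added. Some genes that this rule names are not reported here, though they stayed in every fit, count and list test. Fkbp5, Tsc22d3 and Sult1a1 in the metronidazole comparisons follow from this rule, while the weighing of glucocorticoid targets was chosen after their values were seen.

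Alternatives fixed in advance were the pseudocounts 0.5 and 5, upper-quartile rescaling, quantile normalization, a robust variance model, library weights, a covariate of other-cell markers, a fit of only the groups compared, and leaving out each library in turn. After the data were seen, these were added: WT metronidazole libraries 4 and 5 left out together, the summed satellite-like gene models as a covariate, a minimum mean of 200, a correction for GC content and transcript length (2944 genes matched to GENCODE M21), and the letter of the code in each library's description as a term. The letter term was added last, when the counts and the splits of the libraries were known. Satellite-like and mitochondria-like gene models were found by shared short sequences with a reference model, at least 10% of them.

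Principal components were first computed without 13 genes of large spread, Cst7 and Apoe among them. No fixed choice called for that, so the values reported use all genes. Without the 13 genes the first component held 22.6% of the variance in place of 21.6%, and its exact permutation p for metronidazole in 5XFAD was 0.0476 in place of 0.0714, adjusted p = 0.152 in place of 0.181 (n = 5 and 5).

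The fit was tested on simulated data of the same groups, with each gene's mean and spread and no correlation between genes. With a threshold of 0.05 it recovered 40.3% of 67 genes shifted by 0.5 log2 units, 86.6% of 67 shifted by 1 and 100% of 66 shifted by 2, and 9 of 160 calls were of genes not shifted. Where fewer genes are called than the 160 here, the adjusted threshold asks for smaller p-values. The shares recovered may therefore not hold for the real comparisons. Camera gave a raw p under 0.05 to 11 of 200 lists that held no shift, and correlated genes, as real lists hold, were not simulated. Single libraries far from their group were looked for in the printed gene levels and in the library measures, 68 groups in all.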

Results

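RNA was measured in microglia, the resident macrophages of the brain, sorted from wild-type (WT) mice and from 5XFAD mice, a transgenic model of Alzheimer's disease. The sample descriptions name the WT mice C57BL6-SJL and the 5XFAD mice 5XFAD-SJL. From 9 months of age the mice drank plain water or water with metronidazole, an antibiotic against anaerobic bacteria. The study's description gives the dose as 200 mg/mL for 7 days and 40 mg/mL for the next 9 weeks, and whether the unit is as meant could not be checked. Genotype and drinking water make 4 groups of 5 libraries, 20 libraries in all, each from 1000 sorted cells. The deposited table holds normalized counts of 2969 named genes, and the reads behind them are not given, so the sequencing depth per library is unknown. Summed over the table, a library held between 1655880 and 3502550 normalized counts. Gene models that resemble mouse satellite repeats, 11 in number, took 51.3% of these on average, from 33.8% in metronidazole-treated WT library 4 to 68.3% in metronidazole-treated WT library 2. In 5XFAD their share was 45.6% ± 7.86 (SD, n = 5) with metronidazole and 56.6% ± 3.72 (n = 5) on water (exact permutation p = 0.0238, adjusted p = 0.127 over 16 tests of library measures). Libraries of the same group correlated with a median Pearson r of 0.919 across genes (lowest 0.826, highest 0.952), against 0.908 for libraries of different groups.

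**Figure D1:**
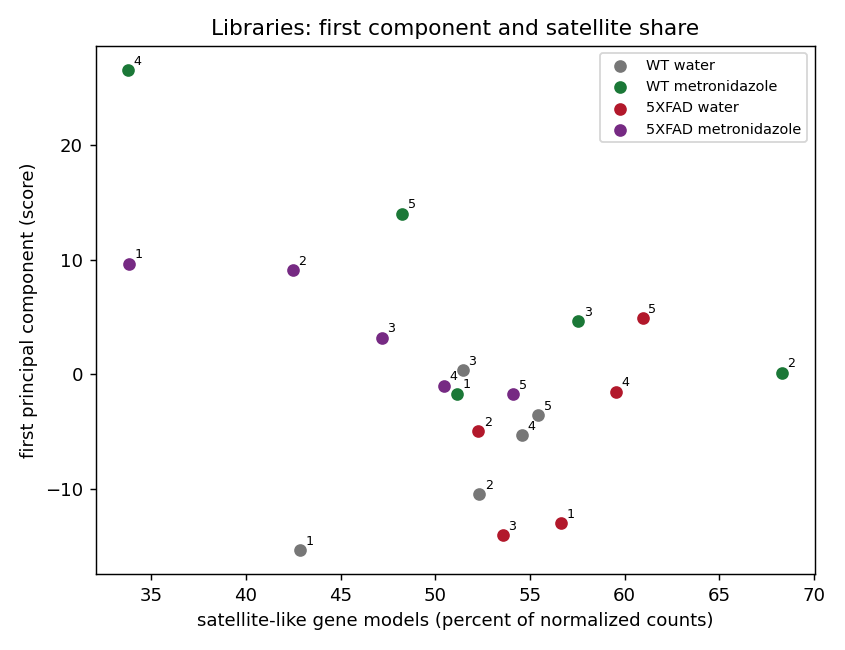
Score on the first principal component of the log2 normalized counts (vertical axis, no unit) against the percent of normalized counts in 11 satellite-like gene models (horizontal axis), with 1 point per library, coloured by group and numbered by replicate. Metronidazole-treated WT libraries 4 and 5 have the highest scores, 26.6 and 14.0, and the 5 WT libraries on water lie between -15.3 and 0.35.

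The first principal component held 21.6% of the variance. Its score was higher with metronidazole than on water in WT, with means of 8.74 and -6.87 (exact permutation p = 0.0238, adjusted p = 0.127, n = 5 and 5). In 5XFAD the means were 3.85 and -5.72 (exact permutation p = 0.0714, adjusted p = 0.181, n = 5 and 5). Each library's description carries a code of a letter and a number, whose meaning is not stated, and the letter follows the treatment. On water, 3 WT libraries carry D and 2 carry E, and all 5 5XFAD libraries carry E. With metronidazole, 3 WT libraries carry E and 2 carry F, and all 5 5XFAD libraries carry F. Values between libraries of the same letter are therefore given beside the results below, where such libraries exist. They equal the changes fitted with the letter as a term. In such fits the difference of F from E is measured only between metronidazole-treated WT libraries 4 and 5 and libraries 1, 2 and 3. For 5XFAD it is carried over from them.

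The comparison of 5XFAD with WT on water asks what the transgenes change in microglia when no antibiotic is given. The genes that passed belong mostly to the disease-associated state, a program described in microglia near amyloid plaques. Cst7, which encodes the protease inhibitor cystatin F, averaged 673 ± 316 normalized counts in 5XFAD and 18.9 ± 12.999 in WT (SD, n = 5 each), a fold of 35.7. Apoe, which encodes a lipid carrier, averaged 8259 ± 3049 and 624 ± 299, a fold of 13.2. Lyz2, a lysozyme gene, averaged 781 ± 258 and 245 ± 78.2, and Cd63, a tetraspanin of late endosomes and lysosomes, 682 ± 162 and 340 ± 50.2. Slc2a5, a fructose transporter gene typical of resting microglia, went the other way, with 394 ± 59.7 in 5XFAD and 827 ± 133 in WT. For each of these 5 genes all 5 5XFAD libraries lay on 1 side of all 5 WT libraries (2-sided exact permutation p = 0.00794 for 1 gene, not adjusted, the smallest this test can give).

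**Figure D2:**
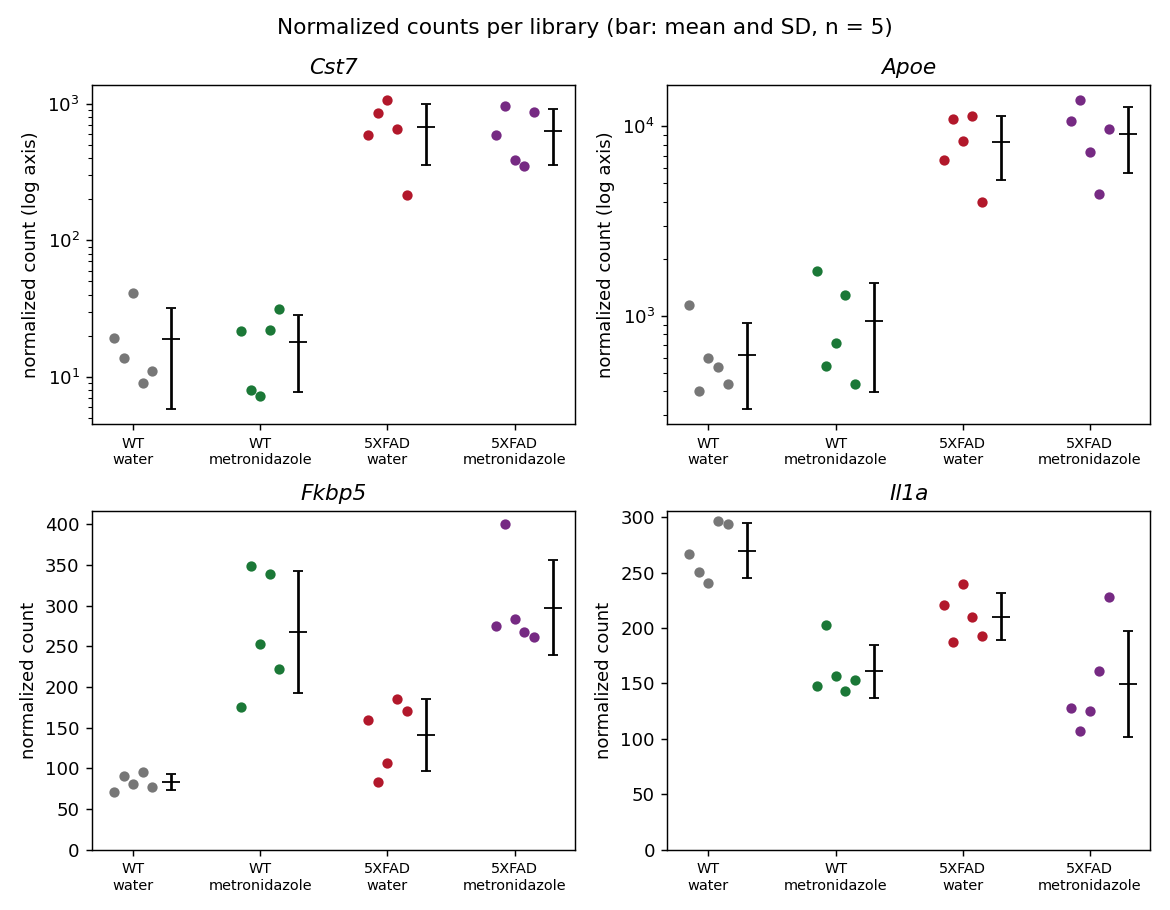
Normalized counts of Cst7, Apoe, Fkbp5 and Il1a in each library (points; vertical axes, logarithmic for Cst7 and Apoe), with the mean and SD of each group of 5 beside the points. On water, Cst7 lies between 214 and 1059 in 5XFAD and between 8.99 and 41.0 in WT, and Fkbp5 in WT lies between 175 and 349 with metronidazole and between 71.3 and 96.2 on water.

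Of the 2969 genes, 8 changed between 5XFAD and WT on water (limma, adjusted p under 0.05), of which 7 rose and 1 fell. A raw p under 0.05 was found for 348 genes, where 148.5 are expected by chance. Cst7 rose by 5.11 ± 0.45 on the log2 scale (SE; adjusted p = 2.26e-07), Apoe by 3.74 ± 0.36 (adjusted p = 7.96e-07) and Lyz2 by 1.64 ± 0.27 (adjusted p = 0.00201). The other genes that rose were Cd83, a surface protein of activated immune cells (1.05), Cd52 (0.98), Cd63 (0.97) and Mif, a cytokine gene (0.80), and Slc2a5 fell by 1.07. Genes of small p that did not pass were Atp13a2 (0.62), Cd9 (0.53), Cxcl16 (0.82), Ccl3 (0.57) and Abca1 (0.47) on the higher side, and Slco4a1 (-0.77), Upk1b (-0.70), Grap (-0.67) and Tuba1a (-0.61) on the lower side, with adjusted p between 0.0553 and 0.0701. The count was 11 (6 higher, 5 lower) without 5XFAD water library 1, 25 without 5XFAD water library 5, 19 without WT water library 1, 15 without WT metronidazole library 4, 17 without WT metronidazole libraries 4 and 5, 28 with library weights, 31 with the satellite level and 27 with GC content and length taken into account (15 higher, 12 lower), and 4 with the code letter as a term. Among the letter E libraries alone (5 5XFAD, 2 WT) all 8 genes kept their direction, with a median change of 1.19 against 1.06 in all libraries. The 8 genes were called with these libraries in, so a kept direction was largely fixed in advance.

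By group on water, all 9 measured members of the stage 1 list of disease-associated microglia were higher in 5XFAD (median 0.44), and the list rose (camera adjusted p = 1.81e-12). Among them 2 passed over all genes and 8 adjusted over the list alone. All 15 measured members of the stage 2 list were higher (median 0.53, camera adjusted p = 1.03e-16), 4 of them past the threshold over all genes and 9 adjusted over the list alone. Both lists were drawn up in the literature on microglia of this mouse model, though not on these libraries. The lipid handling and efflux list rose (9 of 9 higher, camera adjusted p = 4.15e-08), with Apoe past the threshold over all genes and 4 genes adjusted over the list alone. The homeostatic list fell (26 of 30 lower, median -0.22, camera adjusted p = 2.05e-08), with Slc2a5 past the threshold, 2 genes adjusted over the list alone, and Crybb1 (-0.60), P2ry13 (-0.48) and Cx3cr1 (-0.28) not past it. These 4 lists also passed with an estimated correlation, with adjusted p of 0.00486, 0.00448, 0.000688 and 0.00697 in the order given. Apoe stands in both the stage 1 and the lipid list, so these are not separate support.

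Other lists passed camera on water with the preset correlation and not with an estimated one. Lysosomal genes rose (29 of 36 higher, camera adjusted p = 1.82e-07, adjusted p = 0.111 with an estimated correlation). Cd63, also in the stage 2 list, was past the threshold over all genes and 10 genes adjusted over the list alone. Cytoplasmic ribosomal protein genes rose (73 of 78 higher, camera adjusted p = 6.55e-19, adjusted p = 0.148 with an estimated correlation), with 0 past the threshold by limma over all genes and 5 adjusted over the list alone. Glycolysis genes rose (12 of 16 higher, camera adjusted p = 0.00589, adjusted p = 0.132 with an estimated correlation), with 0 genes past the threshold by limma over all genes or adjusted over the list alone; Tpi1 differed by 0.50 and Ldha by 0.33. Immediate early genes, which cell isolation can induce, fell (20 of 23 lower, camera adjusted p = 1.14e-06, adjusted p = 0.148 with an estimated correlation), with 0 over all genes by limma and 5 adjusted over the list alone, and with Nr4a1 at -0.71, Klf2 at -0.63 and Jun at -0.44. Mitochondrially encoded transcripts rose (11 of 12 higher, camera adjusted p = 0.00865, adjusted p = 0.458 with an estimated correlation, 0.126 with the satellite level as a covariate and 0.704 with the code letter as a term), with 0 genes over all genes by limma or adjusted over the list alone. The class I (adjusted p = 0.105), class II (adjusted p = 0.290) and inflammatory (adjusted p = 0.290) lists did not pass camera, and neither did the phagocytic (0.299), nuclear oxidative phosphorylation (0.981), p53 (0.0690), NRF2 (0.481), microbial sensing (0.981) and TGF-beta (0.981) lists. Of the interferon response, cell cycle, alternative activation and cholesterol synthesis lists 3, 2, 2 and 0 genes were measured, too few for the test.

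The same genotype comparison in metronidazole-treated mice asks whether the 5XFAD difference is there under the antibiotic. Cst7 averaged 632 ± 277 normalized counts in 5XFAD and 18.1 ± 10.4 in WT (SD, n = 5 each), a fold of 34.9, and Apoe 9159 ± 3509 and 943 ± 545, a fold of 9.72. Lyz2 averaged 780 ± 280 against 245 ± 50.8, Cd63 735 ± 135 against 343 ± 42.4, and the chemokine gene Ccl3 1302 ± 140 against 723 ± 57.3. All 5 5XFAD libraries lay above all 5 WT libraries for each of these 5 genes (exact permutation p = 0.00794 for 1 gene, not adjusted).

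With metronidazole, 28 genes changed between 5XFAD and WT (limma), 24 up and 4 down, and 382 had a raw p under 0.05. Cst7 rose by 5.14 ± 0.45 (SE; adjusted p = 2.04e-07), Apoe by 3.37 ± 0.36 (adjusted p = 5.33e-06), Ccl6 by 1.36 ± 0.21 (adjusted p = 0.00116) and Ccl4, a chemokine gene, by 1.05 ± 0.18 (adjusted p = 0.00177). Lyz2 (1.60), Dpp7 (1.28), Cd83 (1.17), Cd63 (1.09), Rab8a (1.02), Tmem104 (1.01), the cathepsin genes Ctsb (0.86), Ctsd (0.63) and Ctsz (0.51), the lysosomal cholesterol carrier Npc2 (0.60), the pattern receptor Tlr2 (0.62), the ferritin gene Fth1 (0.50) and the interferon-related Lgals3bp (0.93) also rose. The genes that fell were Map4k4 (-0.73), Tspan18 (-0.71), Klhdc8b (-0.67) and Sall1, a transcription factor of microglial identity (-0.43). The genes called in both genotype comparisons were 6, Apoe, Cd52, Cd63, Cd83, Cst7 and Lyz2, all in the same direction, where 0.0579 in the same direction are expected by chance. Across all genes, which are not independent replicates, the log2 changes in the 2 comparisons correlated with Pearson r = 0.344 and Spearman rho = 0.0892, and 49.1% had the same sign. The count was 12, 14 and 15 without 5XFAD metronidazole libraries 2, 1 and 5, 15 and 14 without WT metronidazole libraries 2 and 3, 44 without WT metronidazole libraries 4 and 5, 65 with library weights, 16 with the markers of other cells as a covariate, 16 with only the groups compared and 68 with the code letter as a term. Among the letter F libraries alone (5 5XFAD, 2 WT) all 28 genes kept their direction, with a median change of 0.81 against 0.80 in all libraries. The 28 genes were called with these libraries in, so a kept direction was largely fixed in advance.

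The stage 1 list of disease-associated microglia rose with metronidazole too (9 of 9 higher, median 0.55, camera adjusted p = 4.68e-14), with 5 genes past the threshold over all genes and 8 adjusted over the list alone. The stage 2 list rose (15 of 15 higher, median 0.69, camera adjusted p = 9.07e-21), with 7 over all genes and 13 adjusted over the list alone. Lysosomal genes rose (31 of 36 higher, camera adjusted p = 1.77e-13), with 5 over all genes and 15 adjusted over the list alone, and so did lipid handling (8 of 9 higher, camera adjusted p = 2.30e-05; 2 over all genes and 2 adjusted over the list alone). Inflammatory genes rose (11 of 17 higher, camera adjusted p = 4.39e-05), with Ccl3, Ccl4 and Tlr2 past the threshold and 6 adjusted over the list alone; with the code letter as a term their adjusted p was 0.0795. Glycolysis genes rose (14 of 16 higher, camera adjusted p = 3.27e-05), with 0 past the threshold by limma over all genes and 6 adjusted over the list alone. These 6 lists passed with an estimated correlation, with adjusted p of 0.00275, 0.00275, 0.0158, 0.00275, 0.0136 and 0.0220 in the order given. They share genes. Ctsb, Ctsd, Ctsz and Cd63 stand in a disease-associated list and in the lysosomal list. Apoe stands in the stage 1 and lipid lists, and Npc2 in the lysosomal and lipid lists. The rises of these lists are therefore not separate findings.

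The lists of phagocytic receptors (21 of 24 higher, camera adjusted p = 3.27e-05), cytoplasmic ribosomal proteins (75 of 78 higher, 7.85e-17), nuclear oxidative phosphorylation (24 of 38 higher, 0.0462) and NRF2 targets (8 of 9 higher, 0.0255) also rose with the preset correlation, and immediate early genes fell (13 of 23 lower, 0.0480). Their adjusted p with an estimated correlation was 0.0754, 0.199, 0.444, 0.199 and 0.465, and with the code letter as a term it was 0.894 for the ribosomal, 0.691 for the NRF2 and 0.691, in the other direction, for the oxidative phosphorylation list. In these lists 1, 0, 0, 1 and 0 genes passed over all genes by limma, and 4, 0, 0, 2 and 5 (1 higher, 4 lower) adjusted over the list alone. The homeostatic list did not pass (22 of 30 lower, camera adjusted p = 0.146).

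**Figure D3:**
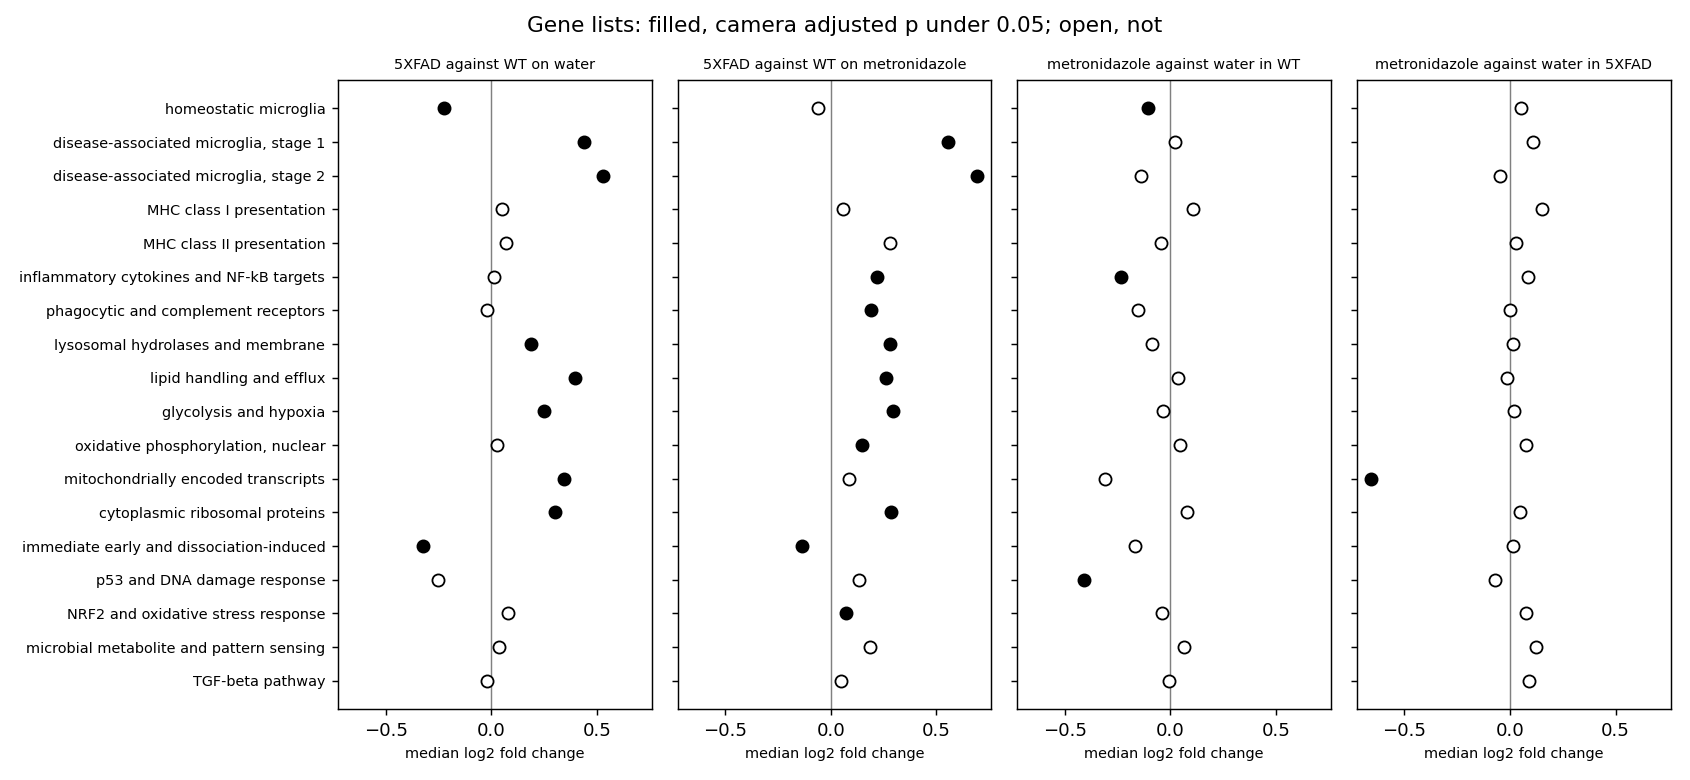
Median log2 fold change (horizontal axes) of the measured members of 18 gene lists in 4 comparisons; filled points passed camera with a preset correlation at an adjusted p under 0.05, and open points did not. The stage 2 list of disease-associated microglia lies at 0.53 and 0.69 in the genotype comparisons and at -0.14 and -0.05 in the metronidazole comparisons, and the mitochondrially encoded transcripts lie at -0.66 with metronidazole in 5XFAD.

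The comparison of metronidazole with water in WT asks what the antibiotic changes in microglia without the transgenes. Fkbp5, a co-chaperone gene that glucocorticoids induce, averaged 268 ± 75.2 normalized counts with metronidazole and 83.4 ± 10.1 on water (SD, n = 5 each), a fold of 3.21. Il1a, which encodes the cytokine interleukin-1 alpha, averaged 161 ± 23.9 against 270 ± 25.0. For both genes all 5 treated libraries lay on 1 side of all 5 water libraries (exact permutation p = 0.00794 for 1 gene, not adjusted). P2ry12, a purine receptor gene typical of resting microglia, was lower, at 2716 ± 418 against 4116 ± 828. Stab1, a scavenger receptor gene also used as a marker of border-associated macrophages, averaged 1707 ± 512 against 899 ± 235.

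In WT, 71 genes changed with metronidazole (limma), 37 up and 34 down, and 629 had a raw p under 0.05. The count was 1 with only the groups compared in the fit. It was 2 without WT metronidazole libraries 4 and 5, where all 71 genes kept their direction and their median change was 0.61 against 0.72, and 0 by limma with the code letter as a term (161 genes at a raw p under 0.05). Fkbp5 rose by 1.63 ± 0.21 (SE; adjusted p = 0.000253) and passed in 31 of 32 other settings, with adjusted p from 5.58e-05 to 0.248. The exception was the code letter as a term, with 1.52 ± 0.31. Tle3 (1.501), Mrc2 (1.12), Ndufb2 (1.08), Wdfy3 (1.05), Agpat3 (1.02), Upf3a (0.99), Dnajb13 (0.99), Ppp1r21 (0.99), Lars2 (0.98) and Stab1 (0.91) rose, with adjusted p from 0.0239 to 0.0479. Hpgd, a prostaglandin-degrading enzyme gene (-1.03), Capza2 (-1.01), Arl8b (-0.93), Cmtm6 (-0.89), the clathrin heavy chain gene Cltc (-0.79), Cd53 (-0.78), Pros1 (-0.78), Atp6v1b2 (-0.76), Il1a (-0.75) and Cd48 (-0.72) fell, with adjusted p from 0.0265 to 0.0482. Of the homeostatic genes, P2ry13 (-0.62), P2ry12 (-0.59) and Slc2a5 (-0.57) fell. In WT, P2ry12 passed in 18 and Slc2a5 in 20 of 33 other settings. Il1a and Tle3 each passed in 23 of 32, and Stab1 in 23 of 33.

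Leaving out 1 library moved the WT count widely. It was 2 and 1 without water libraries 1 and 2, and 115, 45 and 120 without water libraries 3, 4 and 5. Without metronidazole libraries 1, 2, 3, 4 and 5 it was 189, 42, 30, 4 and 4. Without 5XFAD water library 2 it was 37, and without 5XFAD metronidazole libraries 2 and 3 it was 40 and 35. It was 3 with library weights, 2 with the markers of other cells as a covariate and 129 with the satellite level as a covariate. The marker covariate is the mean of the marker scores, among which Ttr varies most and Stab1 is itself a called gene. Ttr differed by -3.21 on the log2 scale with metronidazole in WT (SD 3.52 treated, 1.48 on water). The drop to 2 is therefore no measure of other cells alone. Among the letter E libraries alone (3 treated, 2 on water) all 71 genes kept their direction, with a median change of 0.46 against 0.72 in all libraries. In the same libraries Fkbp5 differed by 1.52, Il1a by -0.81, P2ry12 by -0.29 and Stab1 by 0.28. The 71 genes were called with these libraries in, so a kept direction was largely fixed in advance. These differences equal the changes with the code letter as a term and are not a separate check.

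The homeostatic list fell with metronidazole in WT (22 of 30 lower, median -0.11, camera adjusted p = 0.0370), with 4 genes past the threshold over all genes and 7 down and 1 up adjusted over the list alone. The inflammatory list fell (12 of 17 lower, camera adjusted p = 0.0475), with Il1a past the threshold over all genes and adjusted over the list alone. The p53 list fell (6 of 6 lower, median -0.41, camera adjusted p = 0.0119), with Sesn1 (-0.58) and Btg2 (-0.48) past the threshold and 3 genes adjusted over the list alone. Most genes of the p53 list were not measured, and Btg2 stands in the immediate early list too. None of the 3 passed with an estimated correlation, with adjusted p of 0.489, 0.410 and 0.0543, and with the code letter as a term their adjusted p was 0.458, 0.00113 and 0.195. The disease-associated lists did not pass (stage 1 adjusted p = 0.811, stage 2 adjusted p = 0.0825), and neither did class I (0.383) or class II (0.853).

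The comparison of metronidazole with water in 5XFAD asks whether the antibiotic alters microglia in the disease model. No gene passed (0 of 2969 by limma, 267 at a raw p under 0.05, lowest adjusted p = 0.0575). Fkbp5 averaged 298 ± 58.0 normalized counts with metronidazole and 141 ± 43.8 on water (SD, n = 5 each), a fold of 2.11. All 5 treated libraries lay above all 5 on water (exact permutation p = 0.00794 for 1 gene, not adjusted). Fkbp5 was named for its small limma p in these same libraries, so the separation is no separate check. The log2 change of Fkbp5 was 1.12 ± 0.21 and that of Sult1a1, a sulfotransferase gene, 0.75 ± 0.15 (SE, limma adjusted p = 0.0575 for both). Tsc22d3, another glucocorticoid-induced gene, averaged 505 ± 36.4 against 320 ± 71.8 (log2 change 0.68, limma adjusted p = 0.116). The other genes of smallest p were Tmem104 (0.89) and Rcan1 (0.69) on the higher side and Itch (-0.61), Cntrl (-0.65), Rab1a (-0.61), Il1a (-0.53) and Slc38a2 (-0.53) on the lower side. Fkbp5 passed in 8 of 32 other settings, with adjusted p from 0.0150 to 0.455. Cst7 and Apoe had log2 changes of -0.03 and 0.15 with metronidazole in 5XFAD. The count was 2 with upper-quartile rescaling, with quantile normalization, without WT metronidazole libraries 4 and 5, without WT metronidazole library 5 and without 5XFAD water library 5, and 1 without WT metronidazole library 1 or 5XFAD water library 1 or 4, and 6 with library weights.

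Of the lists in 5XFAD, mitochondrially encoded transcripts fell with metronidazole (12 of 12 lower, median -0.66, camera adjusted p = 1.37e-05), with 0 past the threshold by limma over all genes or adjusted over the list alone. Their adjusted p was 0.894 with an estimated correlation, 0.275 with the satellite level as a covariate, and 0.00788 in the other direction, a rise with a median of 0.46, with the code letter as a term. In 5XFAD all treated libraries carry the letter F and all water libraries E, so no value within a letter can be had. The letter term there rests on the difference of WT metronidazole libraries 4 and 5 from 1, 2 and 3. mt-Atp8 differed by -1.34, mt-Nd3 by -0.99, mt-Nd2 by -0.83 and mt-Nd1 by -0.77. Mitochondrial transcripts took 0.744% ± 0.175 of the counts outside the satellite-like models with metronidazole and 1.13% ± 0.236 on water (SD, n = 5 each; exact permutation p = 0.0317, adjusted p = 0.127). The homeostatic (adjusted p = 0.774), disease-associated (0.818 for both stages), inflammatory (0.818), class I (0.326) and class II (0.818) lists did not pass.

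Averaged over both genotypes, 63 genes changed with metronidazole (limma), 36 up and 27 down, and 629 had a raw p under 0.05. Fkbp5 rose by 1.37 ± 0.15 (SE; adjusted p = 1.21e-05), Sult1a1 by 0.70 ± 0.10 (adjusted p = 0.00124), Ppp1r21 by 0.81 ± 0.13 (adjusted p = 0.00181) and Ccnd3, a cyclin gene, by 0.67 ± 0.11 (adjusted p = 0.00298). Il1a fell by 0.64 ± 0.11 (adjusted p = 0.00682). Fkbp5, Sult1a1, Ppp1r21 and Il1a each passed in 30 of 31 other settings, and the code letter as a term ended all 4 calls, with changes of 1.25 ± 0.28, 0.90 ± 0.19, 0.71 ± 0.22 and -0.59 ± 0.21. Tle3 (1.02), Agpat3 (0.79), Dnajb13 (0.76), the ion channel gene Trpm2 (0.73), Stab1 (0.72) and Ndufb2 (0.68) also rose. With the code letter as a term these 6 were at 0.42, 0.18, 0.18, 0.31, 0.0532 and -0.0133, and Ccnd3 at 0.66. Gpr34 (-0.92), Hpgd (-0.79), Morc3 (-0.65), Pros1 (-0.60), Cltc (-0.59), Selenof (-0.58), Cmtm6 (-0.57), Tm9sf3 (-0.56), Cd53 (-0.55) and P2ry12 (-0.41) fell. In the fit with the code letter, the 5XFAD part of each average carries over the difference of WT metronidazole libraries 4 and 5 from 1, 2 and 3. With the code letter as a term 5 of the genes that fell turned. Gpr34 went to 0.22, Pros1 to 0.00866, Selenof to 0.0966, Cmtm6 to 0.20 and Cd53 to 0.0165. Hpgd, Morc3, Cltc, Tm9sf3 and P2ry12 were then at -0.35, -0.35, -0.18, -0.43 and -0.17. The averaged change of P2ry12 passed in 12 of 32 other settings. The mitochondrial list fell (11 of 12 lower, camera adjusted p = 0.00107, adjusted p = 0.872 with an estimated correlation), and so did the p53 list (5 of 6 lower, camera adjusted p = 0.0361, adjusted p = 0.169 with an estimated correlation). In each of these 2 lists 0 genes passed over all genes by limma and 3 adjusted over the list alone, and with the code letter as a term the adjusted p was 0.331, in the other direction, and 0.741.

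The averaged count was 0 by limma with the code letter as a term (186 genes at a raw p under 0.05), 9 without WT metronidazole libraries 4 and 5, 6 with the markers of other cells, 14 with the satellite level and 33 with GC content and length taken into account. With upper-quartile rescaling it was 50, of which 35 were higher and 15 lower. Without WT water libraries 1, 2, 3 and 4 it was 23, 22, 95 and 18, and without WT metronidazole libraries 1, 4 and 5 it was 164, 18 and 22. Without 5XFAD water libraries 1, 2, 3 and 5 it was 22, 35, 18 and 135, and without 5XFAD metronidazole libraries 1, 2, 3 and 4 it was 18, 22, 20 and 40.

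The interaction asks whether the response to metronidazole differs between the genotypes. No gene passed (0 of 2969 by limma, 244 at a raw p under 0.05, lowest adjusted p = 0.155). The 3 genes at that adjusted p were Tmem104 (1.35 ± 0.29), Slc2a5 (0.91 ± 0.20) and Tbxas1 (0.66 ± 0.15, SE), and Fkbp5, called in WT and not in 5XFAD, had an interaction of -0.52 ± 0.30 (SE; adjusted p = 0.646). The homeostatic list rose in the interaction (24 of 30 higher, median 0.21, camera adjusted p = 0.0103), as did the inflammatory (13 of 17 higher), phagocytic (19 of 24 higher) and p53 (6 of 6 higher) lists (camera adjusted p = 0.0323 for each). None of the 4 passed with an estimated correlation, with adjusted p of 0.241, 0.241, 0.699 and 0.241, or with the code letter as a term, with 0.0804, 0.506, 0.506 and 0.162. In these lists 0 genes passed over all genes by limma, and 1, 0, 0 and 0 adjusted over the list alone. The log2 changes with metronidazole in WT and in 5XFAD, from separate libraries, correlated across genes with Pearson r = 0.403 (0.161 without WT metronidazole libraries 4 and 5) and Spearman rho = 0.315, and 60.0% had the same sign. Of the 71 genes called in WT, 60 moved the same way in 5XFAD.

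The transgenes of this model include human APP under the Thy1 promoter. Mouse App averaged 144 ± 43.1 normalized counts in 5XFAD and 150 ± 42.6 in WT on water (SD, n = 5 each). It passed in none of the 6 comparisons, with a lowest limma adjusted p of 0.211, and Thy1 was not analysed here. Of the markers of other cell types, Lyz2 (monocyte list) was higher in 5XFAD in both genotype comparisons (exact permutation p = 0.00794, adjusted p = 0.0847 over the family), and Ighm (B cell list) was lower with metronidazole in WT by 0.24 (exact permutation p = 0.00794, adjusted p = 0.0847). Stab1 (border-associated macrophage list) was higher with metronidazole by 0.91 in WT and 0.52 in 5XFAD (exact permutation p = 0.0238 and 0.0159, adjusted p = 0.127 and 0.102). Slc1a3 (astrocyte list) was higher with metronidazole in WT by 0.47 (exact permutation p = 0.0159, adjusted p = 0.102), and Pecam1 (endothelial list) was lower in 5XFAD by 0.35 on water and 0.32 with metronidazole (exact permutation p = 0.0397 and 0.0317, adjusted p = 0.127 for both). Csf3r (neutrophil list) and Ttr (choroid plexus list) gave exact permutation adjusted p of 0.127 or more in each comparison. So did the mean of Snhg11 and Calm2 (neuron list), though these went opposite ways with metronidazole in WT. Snhg11 had a fold of 1.23 there and Calm2 of 0.772, with all treated libraries below all on water for Calm2. Markers of oligodendrocytes, T cells and erythroid cells were not analysed here.

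The authors' own comparison tables, at an adjusted p under 0.05, list 41 genes in 5XFAD against WT on water (27 higher, 14 lower), 81 with metronidazole (67 higher, 14 lower), 72 with metronidazole in WT (35 higher, 37 lower) and 67 with metronidazole in 5XFAD (25 higher, 42 lower). All 8 and all 28 limma calls of the genotype comparisons are among the authors' calls, as are 50 of the 71 in WT, and limma called 0 in 5XFAD. Whether the authors' comparisons rest on the same 20 libraries is not stated. Between 95.6% and 96.7% of the shared genes have the same direction in both. For metronidazole in 5XFAD the authors' table gives Fkbp5 a log2 change of 0.83 ± 0.16 (SE; adjusted p = 0.000555), Sult1a1 0.65 ± 0.14 (adjusted p = 0.00242) and Tsc22d3 0.57 ± 0.13 (adjusted p = 0.00725).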

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

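The tests of the label letter, of mitochondrial transcripts in WT and of WT metronidazole libraries 4 and 5, the satellite share and GC content as settings were chosen only after the results were seen.

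In 8 of 68 groups of 5 libraries, 1 library lay far from the other 4 by Dixon's test. Its bound is meant to give about 1 in 20 groups for normally distributed values, which was not checked here. On water, 5XFAD library 1 had 219.5 normalized counts of App, 5XFAD library 4 had 1883 of Ttr, a choroid plexus gene, and WT library 1 had 1140.03 of Apoe. With metronidazole, WT library 1 had 334 of Lyz2, WT library 2 had 203 of Il1a and 422 of Ttr, WT library 4 had 798 of Slc2a5, and 5XFAD library 2 had 400.5 of Fkbp5.

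By camera with the preset correlation 4 lists passed on the interaction, at adjusted p = 0.0103 for homeostatic genes and 0.0323 for the inflammatory, phagocytic and p53 lists. None of these passed with an estimated correlation. With fry their adjusted p was 0.0827, 0.0928, 0.400 and 0.0654, and by camera with the code letter as a term 0.0804, 0.506, 0.506 and 0.162. By limma 0 of 2969 genes passed, so a response that differs between the genotypes is not established.

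The authors' tables hold genes that were not analysed here from the count table and pass there at an adjusted p under 0.05. For metronidazole in WT these are, gene models with clone-type names left out, Brca2, with a log2 change of 0.72, and Ccdc88b, with 0.67. For 5XFAD against WT they are Ank (1.17), Aplp2 (0.58) and Axl (1.57) on water, and Brca2 (-0.57) and Dcbld2 (-0.54) with metronidazole.

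Splits of the 10 libraries compared into other groups of 5 and 5 were used to ask whether chance can be excluded for each count. For 5XFAD against WT on water, with 8 genes, 2 of 100 splits, the real one among them, were as large. The highest other split gave 31. With metronidazole, with 28 genes, 2 of 100 splits were as large, and the highest other split gave 146. Both shares lie under the bound of 5 in 100, but they are not adjusted over the comparisons. Since another split called more genes each time, chance is unlikely but not excluded for these counts. For metronidazole in WT the 71 genes had 4 of 100 splits as large and a highest other of 140. That share lies just under the bound of 5 in 100 and is not adjusted over the comparisons. Neither chance nor a structure of the samples can be excluded by it. The split of 146 genes points to a structure of the samples. It sets WT metronidazole libraries 4 and 5 and 5XFAD metronidazole libraries 1, 2 and 3 against the other 5. The satellite share separates the sides fully, with 33.8% to 48.2% in the former and 50.4% to 68.3% in the other 5. The split of 140 genes differs from the real one only by the exchange of WT water library 5 and WT metronidazole library 1, and that of 31 genes by the exchange of WT water library 1 and 5XFAD water library 5, so that 4 of 5 libraries on each side keep their real group. The other WT splits above 71, of 83 and 88 genes, both set WT metronidazole libraries 1, 4 and 5 with 2 water libraries against the rest, so groupings that do not follow the treatment also call more genes than the treatment does. For the average chance alone is unlikely, with 63 genes, 1 of 100 splits, the real one, as large and a highest other of 2. A structure that follows the treatment, as the label letter does, cannot be excluded. With the letter as a term the averaged count was 0 by limma. The counts of 0 by limma for metronidazole in 5XFAD (267 genes at a raw p under 0.05; 100 of 100 splits as large, highest other 3) and for the interaction (244 genes; 100 of 100, highest other 1) cannot tell.

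The first pattern is the 71 genes that changed with metronidazole in WT. Their median log2 change in the called direction was 0.72. The share of it kept after correction for GC content and length was 0.865, which argues against these as the whole cause. Without WT metronidazole libraries 4 and 5 the share kept was 0.849. The 71 genes were called with these libraries in, so that share was partly fixed in advance and cannot exclude them as the source. Only 2 genes passed without them, with a median change of 0.61 and a median SE of 0.19 against 0.17. Over all genes, 367 then had a raw p under 0.05 by limma, against 629. A library composition that follows the satellite share stays open: 0.9998 was kept with that covariate, but its mean log2 level was the same in both WT groups (20.17 and 20.17), so the bound first written could not have been missed. The letter of the label code cannot be told apart from the treatment, since with it as a term the share kept was 0.639 (0.46, median SE 0.23) and 0 genes passed by limma (161 at a raw p under 0.05), while all 71 kept their direction; the genes were chosen with all libraries in, so these shares rest partly on the same libraries. A response shared by both genotypes stays open too: 84.5% of the genes moved the same way in 5XFAD, but 20 of 100 splits of the 5XFAD libraries reached as much (highest 94.4%), and the bound first written, which would have counted this against the response, was dropped after the value was seen because a share that other splits also reach excludes nothing.

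The second pattern is the lower level of mitochondrially encoded transcripts with metronidazole in 5XFAD, with a median log2 change of -0.66. Reads shared with nuclear copies are argued against, since the summed level of the transcripts and copies together was lower as well, by a log2 change of -0.55 ± 0.19 (SE). A library composition that follows the satellite share may account for most of it, since 0.314 of the median was kept with that covariate (-0.21). The label letter, which all 5 treated libraries carry as F and all 5 water libraries as E, stays open too. With it as a term the share kept was -0.698, a median of 0.46 in the other direction. That term takes the difference of F from E only from WT metronidazole libraries 4 and 5 against 1, 2 and 3. Within 5XFAD the letter cannot be told apart from the treatment. A response to metronidazole also stays open, with a median of -0.31 in WT, which passed camera before adjustment and not after (adjusted p = 0.0922 over 18 lists). That WT value leans on metronidazole libraries 4 and 5, with the lowest mitochondrial shares in WT, 0.324% and 0.536%. Metronidazole libraries 1, 2 and 3 had 0.828%, 0.884% and 1.10%, against a mean of 0.829% in WT on water.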

How the results depend on the processing

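The settings without WT metronidazole libraries 4 and 5, with the satellite level, with GC content and length and with the label letter were chosen only after the results were seen. Counts below are of changed genes in the order 5XFAD against WT on water, the same with metronidazole, metronidazole in WT, in 5XFAD, averaged, and the interaction, where the reported counts were 8, 28, 71, 0, 63 and 0, and comparisons not named stayed within 1.5 times. With library weights the counts were 28 on water, 65 with metronidazole, 3 in WT, 6 in 5XFAD and 2 for the interaction. With the other-cell markers as a covariate they were 16 with metronidazole, 2 in WT, 6 averaged and 1 for the interaction. Ttr has the widest spread in that covariate, which also holds the called genes Stab1 and Lyz2, so it does not measure other cells alone. Without WT metronidazole libraries 4 and 5 they were 17, 44, 2, 2, 9 and 1, and the correlation of the metronidazole effects across genes was 0.161 in place of 0.403; this setting holds fewer samples. With the satellite level they were 31 on water, 129 in WT and 14 averaged, and with GC content and length 27 on water, 33 averaged and 1 for the interaction. With only the groups compared, which leaves fewer samples, they were 16 with metronidazole and 1 in WT. Upper-quartile rescaling and quantile normalization each gave 2 in 5XFAD. Of the 108 list tests, 30 passed as reported, 10 with an estimated correlation and 19 with fry.

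With the label letter as a term the counts were 4 on water, 68 with metronidazole, 0 by limma in WT (161 at a raw p under 0.05) and 0 averaged (186). It turned the averaged change of Cd53 to 0.0165, Cmtm6 to 0.20, Gpr34 to 0.22, Ndufb2 to -0.0133, Pros1 to 0.00866 and Selenof to 0.10. It also turned 3 lists, nuclear oxidative phosphorylation in 5XFAD against WT with metronidazole (adjusted p = 0.691) and mitochondrial transcripts with metronidazole in 5XFAD (adjusted p = 0.00788) and averaged (adjusted p = 0.331). For 5XFAD the letter term carries over the difference of WT metronidazole libraries 4 and 5 from 1, 2 and 3. Except for the smaller number of samples where named, the cause was not tested.

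Leaving out each library in turn gave 6 to 25 genes on water, 12 to 35 with metronidazole, 1 to 189 in WT, 0 to 2 in 5XFAD, 18 to 164 averaged and 0 to 1 for the interaction. The lists passing ranged from 24 to 35, the correlation of the genotype effects from 0.238 to 0.452 and that of the metronidazole effects from 0.271 to 0.502. Over all other settings together, 11248 values of the named genes and lists kept direction and side of the threshold. Of the rest, 786 lost the call, 182 gained it, 173 moved and 9 reversed. Both pseudocounts, the robust variance model and a minimum mean of 200 kept every count within 1.5 times. Cst7, Apoe and Cd83 passed in all 33 other settings of both genotype comparisons. An Xist covariate was not run because that gene was not analysed here, and filters of none and of at least 50 remove no gene. DESeq2 and edgeR were not run because the counts were not recovered, and of the rescalings only the upper quartile was run. The unknown depth limits what can be said of genes not listed.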

Other observations

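The test of shrinkage was chosen only after the fold changes were seen, and that of the glucocorticoid targets after Fkbp5 and Tsc22d3 were seen and before its own result.

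Mitochondrially encoded transcripts took 0.829% of the counts outside the satellite-like models in WT on water, 0.734% in WT with metronidazole, 1.13% in 5XFAD on water and 0.744% in 5XFAD with metronidazole. Among the letter E libraries alone, their median log2 change between 5XFAD and WT was 0.04, and among the letter F libraries 0.61.

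Fkbp5 was higher with metronidazole in both genotypes and Tsc22d3 in 5XFAD, and both are induced by glucocorticoids, so higher glucocorticoid receptor activity may be a candidate explanation. Of a list of 35 targets, 14 were measured once Fkbp5, Tsc22d3 and Sult1a1 were left out. Their median log2 change averaged over the genotypes was 0.0409 (camera adjusted p = 0.608 over the 3 comparisons), with 8 of 14 higher. In 5XFAD it was 0.11 (camera adjusted p = 0.162) and in WT -0.04 (camera adjusted p = 0.608). Members that go both ways decide nothing here, and the hypothesis stays open.

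The log2 changes of Cst7 and Apoe between 5XFAD and WT on water were 5.11 and 3.74 from the normalized counts, and 1.19 and 1.45 in the authors' tables. Shrinkage of large fold changes in those tables could account for this. The median ratio of the authors' value to that of the group means was 0.231 on water (3 genes) and 0.350 with metronidazole (2 genes) past 2 log2 units, against 0.770 and 0.761 for changes under 1 log2 unit. The genes past 2 log2 units are few.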
